A study of Mus musculus with 2 samples.

How the data were processed

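Open chromatin was measured by DNase-seq, in which nuclei are treated with the nuclease DNase I and the DNA ends it leaves are sequenced, so that accessible DNA gives many reads. The 2 libraries were made from heart tissue of female B6CASTF1/J mice aged 2 months. B6CASTF1/J animals are the first-generation offspring of C57BL/6J and CAST/EiJ parents, so part of their DNA differs in sequence from the C57BL/6J reference. The labels' descriptions name animal number 5 for heart replicate 1 and animal number 6 for heart replicate 2, while both libraries carry 1 shared donor identifier. They were treated as 2 animals here, and the spread between them may still be partly technical. There is 1 group, so the design holds no contrast between conditions, and the comparisons set animal against animal and each library against random placements or random gene lists.

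Per the labels, positions are on mm10. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here. Per the deposited descriptions, the peaks of each library derive from the filtered alignments of that library alone, so peaks were called per library and not on pooled reads. Each library has 2 deposited peak lists, whose only varying measurement is a peak height in column 7, a signal value given by the authors. The other measurement columns hold the constants 0, -1, -1 and 75 and were not used. The shorter list of each library was the main list. Every one of its peaks has a lowest FDR of 0.001 or less in the library's own track, against 0.05 for the longer list. The authors also deposited a genome-wide track of FDR values (p-values adjusted for multiple testing), which lists positions under 0.05 only. The deposited footprint lists carry the constant 0.01 in a column that the file headers do not explain, so that other value was not used and only footprint positions entered.

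Within each library the heights are whole multiples of 1 step. All of the 66478 peak heights under 1 in heart replicate 1 and all of the 50967 in heart replicate 2 lie within 0.02 step of a whole multiple. The step is 0.00440 in heart replicate 1 and 0.00399 in heart replicate 2, a ratio of 1.10. If a step stands for 1 read, heart replicate 2 was sequenced about 1.10 times deeper. That reading of the step is an inference from the values, and no other measure of sequencing depth was used. Heights are the authors' values and were used to describe and rank peaks. Where heights of the 2 libraries are set side by side, the median log2 ratio over all 14241 protein-coding promoters with a peak in both libraries is 0.01, so no further scaling was applied.

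The genome sequence was GRCm38, the build called mm10, with GENCODE M21 gene models. Peaks counted as shared when they overlapped by at least 1 bp, and the counts were checked with bedtools 2.31.1, which gave 65259 and 64487 shared peaks, equal to those computed here. Chance levels came from 100 placements of the same intervals at random on the sequenced part of the same chromosomes. A promoter peak is a peak within 1000 bp of any annotated transcription start site of the gene, a promoter peak in both libraries need not be the same peak, and a distal peak lies over 1000 bp from every such site of protein-coding and long non-coding RNA genes, antisense RNAs included. Promoter, exon, intron and intergenic classes were assigned by peak midpoint in that order. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

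For 28 gene lists with 454 entries, written before the data were examined, the share of members with a promoter peak in both libraries was compared with 10000 random lists of protein-coding genes of the same size matched on decile of the promoter CpG observed/expected ratio in 1000 bp. The number of shared distal peaks within 10000 bp of the gene body was compared with 10000 random lists matched on gene length. The percentile of a list is its position among those random lists, with ties split evenly, and lists within the highest or the lowest 2.5% were called. Genes are not replicates, so the percentiles describe these 2 libraries and are not p-values. With 28 lists and 2 tails a few calls arise by chance. The lists are cardiac sarcomere, cardiac transcription factors, calcium handling and ion channels, fatty acid oxidation and muscle mitochondria, cardiac stress and fetal genes, immediate early and heat shock, atrial, ventricular, endothelial, fibroblast, smooth muscle and pericyte, macrophage and myeloid, lymphoid, erythroid, epicardial and mesothelial, Schwann cell, adipocyte, skeletal muscle, hepatocyte, neuron, gut and pancreas epithelium, kidney tubule and podocyte, germ cell, housekeeping, developmental regulators of other tissues, circadian clock, imprinted, and X inactivation and escape. Of the list symbols, 3 are not in the annotation: Ctgf, an older name of Ccn2, which is in the list under its current name, Ahsp and Tf.

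Matches of 40 consensus motifs on both strands were counted by match midpoint. Counts per kb in footprints extended by 5 bp were divided by those in the rest of the same peaks, and counts in the central 200 bp of distal peaks by those in 200 bp windows 1000 bp away that held no peak. A motif was called when its log2 ratio exceeded that of every one of up to 50 letter permutations of its consensus in both libraries. The calculations were tested on simulated data. A simulated overlap of 60% was recovered as 60% over 20000 intervals. Of 200 simulated unchanged lists of 20 genes 1.5% were called, and of 200 with the share raised by 40 points 98% were called. These lists were drawn from genes with low starting shares. The 98% therefore does not describe shorter lists, smaller shifts or lists whose matched share is already high. A motif made with a log2 ratio of 1.58 was recovered at 1.51, against a permutation maximum of 0.60.

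Genes were named by a rule fixed beforehand: the 2 members of each list with the highest promoter peaks, by the lower of the percentiles in each library, and, where under 50% of a list had promoter peaks in both, the first 2 members in alphabetical order without any; the 10 genes with the highest promoter peaks; the 10 genes with the most shared distal peaks; the gene nearest each of the 3 highest peaks of each library that the other lacks; and 16 fixed genes. A few genes that the rule names are not reported here. Any other gene named was chosen after its values were seen, mainly to name the members that lack a promoter peak or differ most between libraries. The sarcomere members named outside the rule are Myl3, Ttn, Mybpc3, Csrp3 and Myom2.

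The alternatives chosen beforehand changed the peak list, the overlap rule, the promoter and locus windows, the matching, the flanks, the footprint rules and the height threshold, and left out each library in turn. Removing chromosome Y, removing runs of close peaks and keeping the CpG number of the permuted motifs were alternatives chosen after seeing the data, as were the comparisons of heights per gene list, of runs and of shared promoter windows. Peaks in runs were compared with peaks outside runs in 20 bins of height, and the spread of the difference came from 10000 resamples of windows of 1000000 bp. The alignments and the other signal tracks of the series were not used here, parental alleles were not separated, and expression was not measured. The HNF1 consensus had no match in footprints and is not reported.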

Results

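Accessible chromatin was mapped by DNase-seq in the hearts of 2 female mice, 1 library per animal, called heart replicate 1 and heart replicate 2. Heart replicate 1 held 116294 peaks with summed widths of 24.3 Mb and heart replicate 2 held 91861 peaks with summed widths of 21.8 Mb, a mean of 104078 ± 17277 peaks (SD, n = 2). Some peaks of a list overlap or lie inside another peak, so the summed widths exceed the bases covered. Each such peak was counted on its own, also in distal counts and in runs of close peaks. The median peak was 200 bp wide in both. Median peak height was 0.848 in heart replicate 1 and 0.874 in heart replicate 2, and the highest peaks reached 49.6 and 85.8. The positions listed with an FDR under 0.05 covered 61.6 Mb in heart replicate 1 and 54.8 Mb in heart replicate 2. The labels describe 1 tissue, 1 strain, 1 sex and 1 age, so the questions addressed are which genes and sequences were accessible and how far both animals shared them. Every value given for a library has no replicate of its own.

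The 10 genes whose promoter peaks stood highest in both animals belong to none of the gene lists fixed for the heart. The promoter of Dynlt1b, which encodes a light chain of the dynein motor, had a peak of height 49.6 in heart replicate 1 and 41.9 in heart replicate 2 (chromosome 17, 6429981 to 6430180). The shared promoter of Hjurp, a chaperone of the centromeric histone, and Trpm8, a cold-activated channel, followed with 38.4 and 35.5 (chromosome 1, 88277501 to 88277760). Glo1, encoding glyoxalase 1, had 25.9 and 22.01, and Hnrnpc, encoding an RNA-binding protein, 24.1 and 21.5. The joint promoter of Mplkip and Sugct had 23.6 and 21.1, Add3, encoding a membrane skeleton protein, 22.3 and 21.9, and the joint promoter of Apaf1, which drives apoptosome assembly, and Ikbip 23.1 and 20.8. Across the genome, 65259 peaks of heart replicate 1 (56.1%) overlapped a peak of heart replicate 2, and 64487 peaks of heart replicate 2 (70.2%) overlapped a peak of heart replicate 1. The mean of these 2 shares was 63.2%, with an SD of 9.96. They are 2 directions of 1 overlap between lists of unlike size, so this SD is no spread between animals. With equal numbers of peaks in both lists the shares were 66.2% and 65.6%. Random placements overlapped in 1.59% and 2.06% of cases and in no placement in more than 2.196%. Sharing rose with height, from 14.6% of the lowest 10% of peaks to 98.3% of the highest 10% in heart replicate 1, and from 0.359% to 99.3% in heart replicate 2. Over 62498 pairs of overlapping peaks, heights correlated across peaks with Spearman's rho of 0.828 and Pearson's r of 0.873 on the log2 scale, and 14.6% of pairs differed by more than 2-fold. Peaks are not independent replicates, so no p-value is attached.

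**Figure D1:**
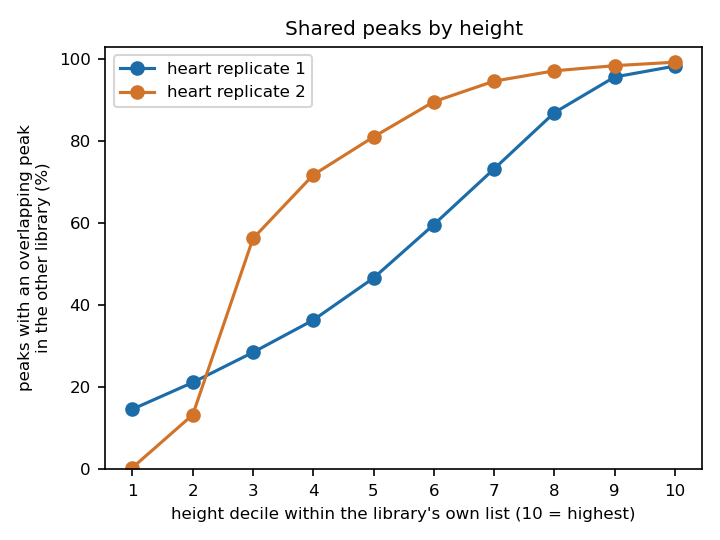
Share of peaks that overlap a peak of the other library (%, vertical axis) by peak height within the library's own list (horizontal axis, 10 equal groups of peaks, 10 being the highest), with 1 line per library. The highest group is shared at 98.3% in heart replicate 1 and 99.3% in heart replicate 2, and the lowest at 14.6% and 0.359%.

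Promoters were the class most enriched in peaks. Promoters of protein-coding and long non-coding RNA genes held 27.6% of the peaks of heart replicate 1 and 32.9% of those of heart replicate 2, a mean of 30.2% ± 3.79 (SD, n = 2), against 4.76% and 4.81% of random placements, which is 5.79-fold and 6.84-fold. Exons held 4.36% and 5.71% of peaks, against 3.21% and 3.24% of placements. Introns held 37.8% and 34.1%, against 40.4% in both, and intergenic sequence 30.2% and 27.3%, against 51.6% and 51.5%. The enrichment of promoters was larger than the spread between the animals. Of 21938 protein-coding genes, 14241 (64.9%) had a promoter peak in both animals, 6794 in neither, 626 in heart replicate 1 only and 277 in heart replicate 2 only. Of 10155 long non-coding RNA genes, 2879 (28.4%) had a promoter peak in both. Among 1466 olfactory and vomeronasal receptor genes, which encode sensory receptors of the nose, 17 had a promoter peak in heart replicate 1 and 8 in heart replicate 2.

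Promoters of contractile, metabolic, endothelial and fibroblast genes were accessible in both hearts. In the sarcomere list, 17 of 20 genes had a promoter peak in both animals, against a mean of 42.4% in CpG-matched random lists. By the lower of the percentiles in each library, Myom1, which encodes myomesin of the M-band, stood highest (18.95 and 15.2 in heart replicates 1 and 2). Myl4, an atrial myosin light chain, followed (13.6 and 18.9) and was above Myom1 in heart replicate 2. The Myom1 peak also lies in the promoter windows of Myl12a and Myl12b, and the Myl4 peak in that of Cdc27. Lower peaks marked Myh6, the main myosin heavy chain of the adult mouse heart (2.49 and 1.09; the gene lies at 54941921 to 54966927 on chromosome 14), Tnnt2, cardiac troponin T (2.04 and 1.03), and Actc1, cardiac actin (2.05 and 1.77). Myh7, the slow myosin heavy chain, had a peak of 0.806 in heart replicate 2 only, Myom2 had one in heart replicate 1 only, and Myl7, the atrial regulatory light chain, had none. The calls of Myh7 and Myl7 changed with the longer peak lists, and that of Myh7 also above the median height. All 20 genes of fatty acid oxidation and muscle mitochondria had a promoter peak in both, such as Acadm, the medium-chain acyl-CoA dehydrogenase (16.01 and 13.3), and Cpt2, which acts in mitochondrial fatty acid import (9.49 and 10.4). So did all 22 endothelial genes, among them Eng, encoding endoglin (5.48 and 5.20), Flt1, a VEGF receptor (3.96 and 4.42), and Pecam1, an endothelial adhesion molecule (1.64 and 1.76). All 20 fibroblast genes had one, including Fn1, fibronectin (4.93 and 6.24), and Col1a1, a chain of type I collagen (4.95 and 5.52). The same held for 19 of 19 housekeeping genes, with Rplp0, a ribosomal protein, at 19.5 and 21.0 and Actb, cytoplasmic actin, at 16.1 and 15.7. It held for 19 of 19 circadian clock genes too, with Nr1d1, the repressor REV-ERBα, at 22.005 and 14.3 and Tef, a D-box binding factor, at 17.96 and 15.8. These 6 lists lay within the highest 2.5% of random lists (percentiles of 100 for sarcomere, fatty acid oxidation, endothelial and fibroblast, 99.0 for housekeeping and 98.5 for circadian clock). The sarcomere call ended when random lists were not matched on CpG (97.3) and the circadian call ended without heart replicate 2 (97.475) and without the runs of close peaks described for private peaks (89.0). In heart replicate 1 alone all 19 clock genes still had a promoter peak. That call was lost only because more random lists also reached the full share.

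**Figure D2:**
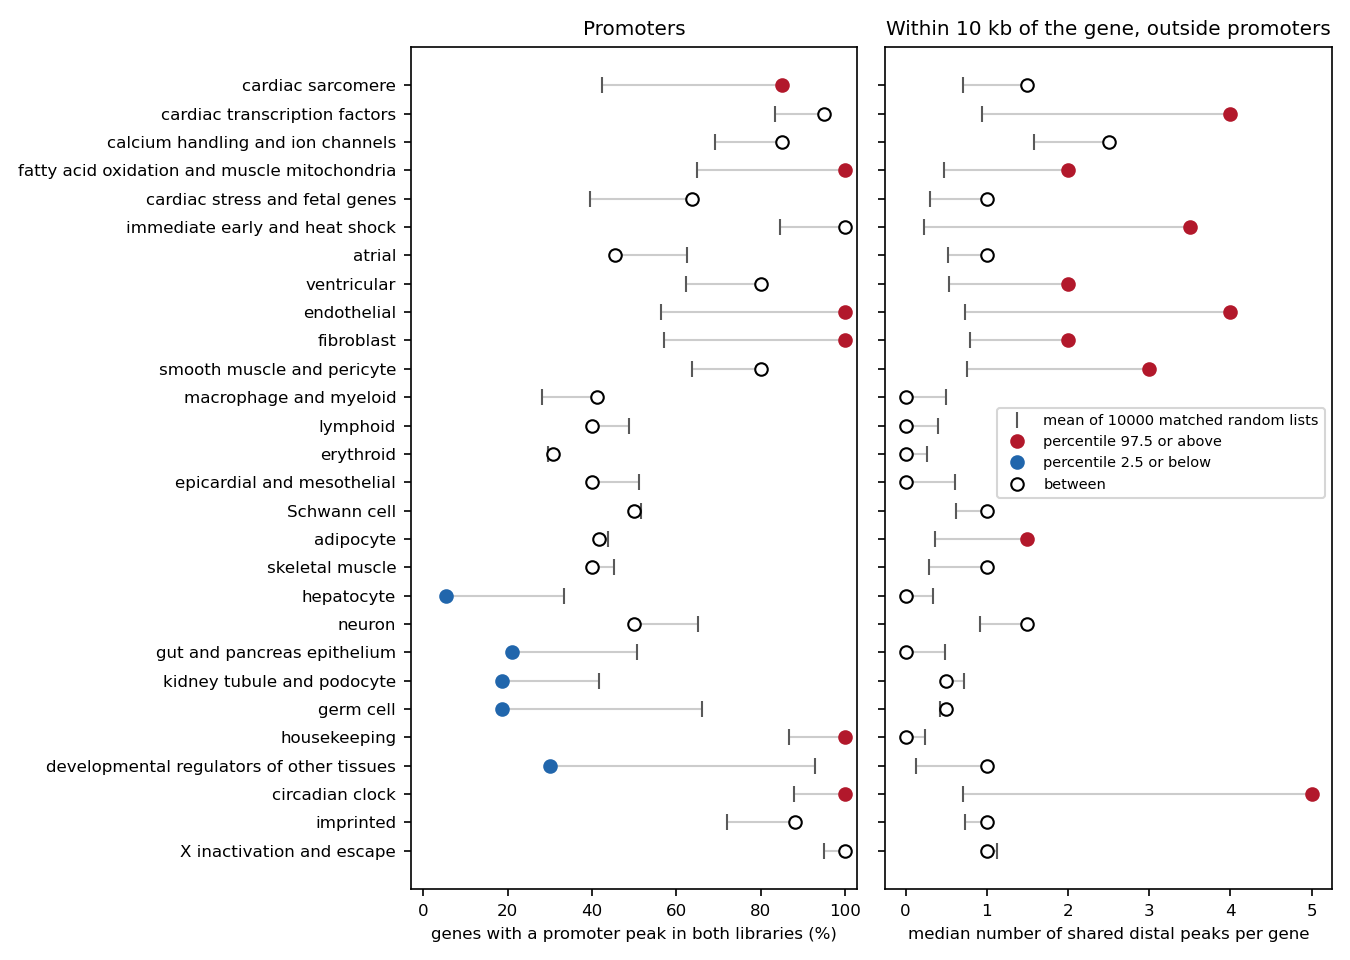
The 28 gene lists. Left, the share of genes with a promoter peak in both libraries (%); right, the median number of shared distal peaks per gene; bars mark the mean of 10000 matched random lists, filled red and blue points are lists within the highest and lowest 2.5% of them, and open points are the others. On the left 6 lists are red and 5 are blue, and on the right 9 are red and none is blue.

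Further cardiac lists did not pass the threshold, and in all of them but the atrial list most promoters were accessible. Promoter peaks in both animals marked 19 of 20 cardiac transcription factors (percentile 95.5), of which Esrra, a nuclear receptor acting on mitochondrial genes, had 25.01 and 16.2 and Mef2a, a muscle transcription factor, 9.75 and 12.2. The heart developmental regulators Gata4 (5.20 and 5.08), Nkx2-5 (2.34 and 2.05), Tbx5 (1.74 and 1.08), Mef2c (3.44 and 3.28) and Hand2 (4.69 and 3.02) all had one, and Hand1 had none. Without the peaks in runs 15 of the 20 had one, against a mean of 82.4% in matched lists (15.75), and Gata4, Tbx5 and Hand2 had one in 1 animal only. Among calcium handling and ion channel genes 17 of 20 had one (97.1), including Atp2a2, the sarcoplasmic calcium pump (8.64 and 9.12), Kcnj2, an inward rectifier potassium channel (9.89 and 8.46), and Ryr2, the calcium release channel (1.956 and 1.48), while Pln and Trdn had one in heart replicate 1 only and Sln had none. The other counts were 7 of 11 stress and fetal genes (95.01), with Rcan1, a calcineurin regulator, at 14.4 and 8.28, Ccn2, a matrix-associated growth factor, at 4.47 and 3.87 and Nppb, the B-type natriuretic peptide, at 1.02 and 1.10. All 12 immediate early and heat shock genes had one (96.2), with Jun at 24.9 and 13.2 and Atf3 at 17.4 and 15.02, both transcription factors induced by stimuli. With ties split, 96.2 is the percentile of a full share in this setting, so this list could not pass there. Ventricular genes reached 8 of 10 (94.3), with the transcriptional regulator genes Hey2 at 12.6 and 13.8 and Lbh at 10.5 and 11.5. Atrial genes reached 5 of 11 (9.54), with Pam, a peptide-processing enzyme, at 7.21 and 7.62, while Nppa, the atrial natriuretic peptide, and Bmp10, an atrial growth factor, had no promoter peak in either main list. Several of these lists passed elsewhere, namely calcium handling in heart replicate 1 alone (99.8), above the median height (98.05) and without runs (97.7), stress and ventricular genes in heart replicate 2 alone (98.4 and 99.2), and cardiac transcription factors and immediate early genes within 250 bp (97.9 and 97.7) and with no CpG matching (99.9 and 99.8). Immediate early genes also passed above the median height (98.8), and without runs 10 of the 12 had a promoter peak (47.7).

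Lists of other organs had few accessible promoters. Of 19 hepatocyte genes only Apob, the main protein of low-density lipoprotein, had a promoter peak in both animals (0.620 and 1.14; percentile 0.270), which lies outside a window of 250 bp, and neither Alb, serum albumin, nor Apoa1, a high-density lipoprotein component, had one in either. Of 19 gut and pancreas genes 4 had one (0.030), the highest being Ins2, insulin (1.93 and 2.13), and Cela1, an elastase (1.99 and 2.37), while Cdh17 and Cdx1 had none. Of 16 kidney genes 3 had one (1.23), Pax2 at 0.901 and 1.401, Cdh16 at 1.08 and 0.255, and Lrp2, while the water channel Aqp2 and the receptor Cubn had none; the kidney call ended without heart replicate 2 (8.19). Of 16 germ cell genes 3 had one (0), and 2 of these peaks also lie in the promoter window of another gene, that of Tex14 with Rad51c and that of Gdf9 with Uqcrq. Ddx4 and Mael, which act in germ cells, had none. Of 20 developmental regulators of other tissues 6 had one (0), against a mean of 93.0% in matched lists, with Lhx2 at 3.46 and 4.004 and Dlx1 at 2.18 and 2.09, while Gbx2 had none. These 5 lists lay within the lowest 2.5%. In heart replicate 1 alone 3 hepatocyte and 5 kidney genes had a promoter peak, and in heart replicate 2 alone 10 developmental regulators, with the hepatocyte and developmental calls kept. With the longer peak lists Aqp2, Mael and Gbx2 gained a promoter peak.

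Lists of the remaining cell types and gene groups lay between these limits when both animals were required. Among smooth muscle and pericyte genes 12 of 15 had a promoter peak in both (92.2), with Smtn, encoding smoothelin, at 9.61 and 6.97 and Mylk, myosin light chain kinase, at 3.73 and 3.37. Macrophage genes reached 7 of 17 (87.9), with Spi1, encoding PU.1, at 2.46 and 1.26 and C1qc, a complement subunit, at 0.945 and 0.942, and none for Aif1 and Cd163. Lymphoid genes reached 6 of 15 (21.4; Lck 4.64 and 6.90, Pax5 2.15 and 2.98, none for Cd3e). Erythroid genes reached 4 of 13 (55.2; Epor 2.00 and 1.83, Rhd 1.27 and 1.95, none for Alas2 and Gata1). Epicardial genes reached 4 of 10 (20.4; Tbx18 3.81 and 1.98, Aldh1a2 1.85 and 3.14, none for Krt8 and Muc16). Schwann cell genes reached 5 of 10 (44.5; Mbp 1.74 and 1.21). Adipocyte genes reached 5 of 12 (44.3; Fabp4 2.37 and 2.65, Pparg 2.14 and 2.93, none for Adipoq and Cfd). Skeletal muscle genes reached 8 of 20 (30.0), and 3 of these peaks lie in another gene's promoter window, among them those of Mylpf (9.67 and 6.00) and Actn3 (7.61 and 12.2), while Acta1, skeletal actin, and Atp2a1, the fast-muscle calcium pump, had none. Neuronal genes reached 10 of 20 (4.31; Nrgn 3.25 and 2.49, Dlg4 2.87 and 2.37). Imprinted genes reached 15 of 17 (96.995), with Cdkn1c, a growth inhibitor, at 7.59 and 6.16 and Peg3 at 8.26 and 6.14. All 8 genes of X inactivation and escape had one (66.8), with Kdm6a, a histone demethylase, at 25.9 and 14.97, Ddx3x, an RNA helicase, at 9.25 and 8.13, and Xist, the RNA of the inactive X, at 1.71 and 1.27. A full share reaches no more than 66.8 in this setting, so this list could not pass there. In heart replicate 1 alone promoter peaks marked 12 of 17 macrophage genes (99.9), 15 of 15 smooth muscle genes (99.87) and 16 of 17 imprinted genes (99.2), which passed, and 10 of 15 lymphoid (87.0) and 7 of 10 epicardial genes (84.7), which did not. Without CpG matching, erythroid (0.820) and skeletal muscle genes (1.24) fell within the lowest 2.5% and X inactivation genes (98.4) and imprinted genes (98.1) within the highest, and within 250 bp skeletal muscle (1.27) and neuronal genes (0.155) fell within the lowest, as did neuronal genes above the median height (0.190). Without runs, imprinted genes passed (97.54). Among the genes named here without a promoter peak, Acta1, Krt8, Muc16, Cd3e, Gata1 and Adipoq gained one with the longer peak lists.

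Distal accessible sites clustered around clock, endothelial, immediate early and cardiac transcription factor genes. The median clock gene had 5 shared distal peaks within 10000 bp, against 0.706 in length-matched lists, with 33 at Rora, a nuclear receptor, and 12 at Nr1d1. The median endothelial gene had 4, against 0.737, with 13 at Pecam1 and 11 at Flt1. The median cardiac transcription factor gene had 4, against 0.936, with 12 at Gata4 and 5 each at Nkx2-5 and Mef2c. Immediate early genes had a median of 3.5, against 0.231, with 4 at Atf3 and 1 at Jun. Smooth muscle genes had 3, fatty acid oxidation, ventricular and fibroblast genes 2 each, and adipocyte genes 1.5. These 9 lists lay within the highest 2.5% and no list within the lowest 2.5%. Sarcomere genes had a median of 1.5 (percentile 95.3) and calcium handling genes 2.5 (89.3), which did not pass with peaks shared by both animals. Counted in 1 animal alone both passed, with sarcomere medians of 5 in heart replicate 1 (99.975) and 4 in heart replicate 2 (99.965) and calcium handling medians of 8 (98.99) and 6 (99.8). Sarcomere genes also passed within 50000 bp (98.9) and with CpG matching (97.8), and calcium handling genes among peaks above the median height (97.59). In 1 animal alone the median also rose to 9 and 7.5 for cardiac transcription factors and to 6 and 8.5 for ventricular genes, in heart replicates 1 and 2, and in heart replicate 1 to 5 for smooth muscle, 3.5 for fibroblast and 2.5 for adipocyte genes. Stress and fetal genes in heart replicate 1 (99.005) and developmental regulators in heart replicate 2 (99.4) passed. The genes with the most shared distal peaks were long ones, led by the readthrough model Gm20388 and followed by Fgfr2, a growth factor receptor whose model is annotated from 130162451 to 133123350 on chromosome 7, with 85, Tns1, a focal adhesion protein gene, with 45, Gse1 with 39 and Rara, a retinoic acid receptor gene, with 34; Ctif and Nav2 had 31 each and Camta1 and Prkce 29 each. The calls for fatty acid oxidation, ventricular, fibroblast and adipocyte genes ended when only peaks above the median height of each list were kept (92.2, 94.7, 93.7 and 97.3). Those for fatty acid oxidation and smooth muscle ended within 50000 bp (91.9 and 96.995), and that for fibroblasts ended with CpG matching (97.1) and without heart replicate 2 (97.4).

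**Figure D3:**
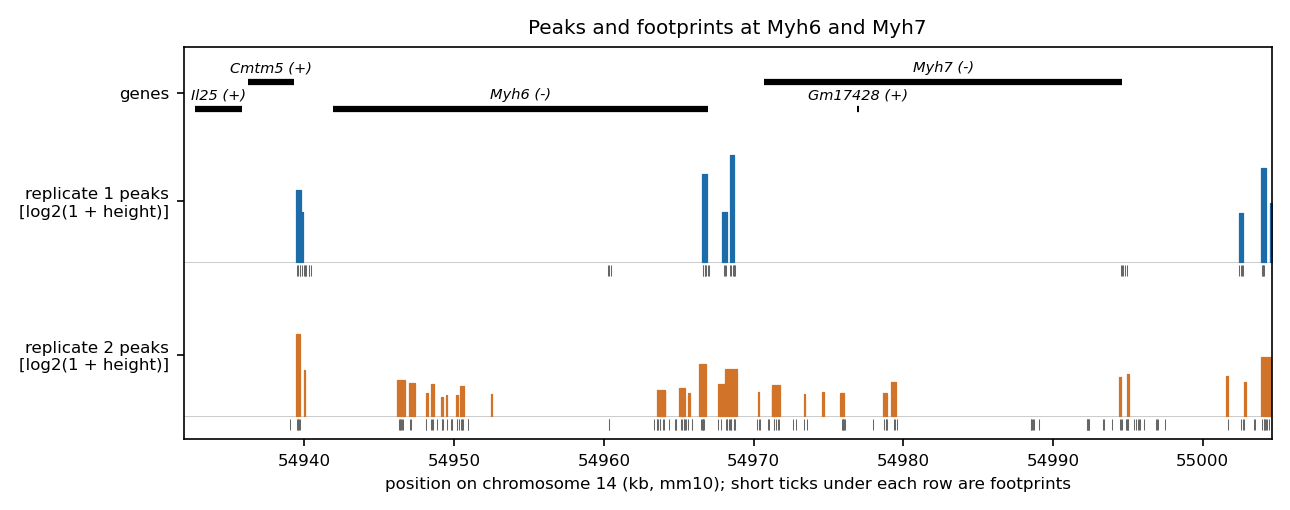
Peaks and footprints around Myh6 and Myh7 on chromosome 14 (position in kb, mm10). Bars are the peaks of each library, drawn as log2(1 + height), with footprints as short ticks under each library and genes at the top; the region holds 8 peaks in heart replicate 1 and 33 in heart replicate 2.

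Footprints, the short protected stretches that the authors called inside accessible DNA, carried the sequences of CTCF, REST, NRF1 and other general factors. Heart replicate 1 had 513221 footprints and heart replicate 2 410185, with median widths of 10 and 9 bp, of which 64.6% and 59.2% lay inside peaks. Of the footprints inside peaks, 36.0% of heart replicate 1 and 51.6% of heart replicate 2 were overlapped by at least 50% of their length in the other library, against 13.1% and 17.1% of footprints placed at random in the peaks. In peaks that both animals share the values were 53.4% and 63.4%, against 21.5% and 26.1%. The CTCF motif, bound by the insulator protein, was denser in footprints than in the rest of the peaks by a log2 ratio of 6.03 in heart replicate 1 and 6.79 in heart replicate 2. The repressor motif REST had 5.44 and 7.29, above CTCF in heart replicate 2, and NRF1, which acts on respiratory chain genes, had 6.73 and 5.93, above CTCF in heart replicate 1. Lower values were those of the cyclic AMP responsive CREB motif with 4.62 and 3.87, the NFI half-site pair with 4.14 and 4.39, SP/KLF with 3.88 and 3.35 and YY1 with 2.23 and 2.30. These 7 of 40 motifs exceeded every letter permutation in both libraries, with SP/KLF having only 8 distinct permutations. The GATA motif was less dense in footprints than around them (log2 ratios of -0.97 and -0.83), as was the FOX motif (-1.13 and -1.11), but neither lay below all of its letter permutations, whose medians were -0.73 and -0.61 for GATA and -0.65 and -0.51 for FOX. The YY1 call ended without the extension of footprints and with permutations that keep the CpG number. Calls were gained by RFX without the extension, and by MEF2 (0.59 and 0.26) and ETS (2.91 and 3.01) with those permutations, so muscle motifs are not excluded from footprints. The height or number of reads in a footprint was not used.

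The centres of distal peaks were dense in CTCF, REST, NFI and CREB motifs. Of the distal peaks, 83157 in heart replicate 1 and 60509 in heart replicate 2, 47.3% and 64.6% were shared, against 78.2% and 81.0% of promoter peaks. The CTCF motif was denser in peak centres than in flanking DNA by log2 ratios of 5.81 and 5.99, REST by 4.89 and 5.27, and the NFI half-site pair by 3.73 and 2.73. MEF2, the motif of muscle transcription factors such as Mef2a, reached 2.07 in heart replicate 1 (1265 matches) and 0.69 in heart replicate 2 (330 matches). The E-box bound by the HAND and TCF21 class reached 1.38 and 1.20, CREB 2.12 and 1.70, SP/KLF 1.15 and 1.09, AP-1, bound by Fos and Jun, 1.36 and 0.76, the glucocorticoid receptor motif 1.19 and 0.84, PU.1 1.33 and 0.61, the endothelial ETS-FOX motif 1.16 and 0.49, and TEAD 0.67 and 0.29. These and RUNX (0.29 and -0.13) and the D-box (0.25 and -0.34) are the 14 motifs above every permutation in both libraries. The RUNX and D-box values lie on both sides of 0, so they stand above their permutations without being denser in the centres of both libraries. In peaks shared by both animals the NFI call ended, and with flanks at 500 bp the glucocorticoid receptor call ended.

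Peaks found in 1 animal only were mostly low. Heart replicate 1 had 51035 such peaks, with a median height of 0.532 against 1.42 for its shared peaks, and heart replicate 2 had 27374, with 0.263 against 1.28. In the other animal's track, 53.1% of the private peaks of heart replicate 1 and 30.1% of those of heart replicate 2 held an FDR under 0.05, against 3.28% and 3.93% of random placements, while 23959 and 19131 held no listed FDR. The highest private peaks lay at promoters that were accessible in both animals. For heart replicate 1 these were peaks at Mbd3, a methyl-CpG binding protein gene (height 19.6; chromosome 10, 80399621 to 80399680), Ppp1r10, a phosphatase regulator gene (17.3), and Cyth2, a guanine exchange factor gene (16.8). For heart replicate 2 they were at Evi5l (16.04; chromosome 8, 4166381 to 4166600), at the Atf3 promoter (15.02; chromosome 1, 191183161 to 191183340), where the nearest 5' end is that of Fam71a, and at Mbd3 (13.96). All 6 positions passed an FDR of 0.001 in the other animal, where the peak lay beside them. In heart replicate 2, 593 runs of at least 10 peaks with gaps of at most 1000 bp held 9411 peaks (10.2%), against 85 runs with 1095 peaks in heart replicate 1, and they held 27.4% of the private peaks of heart replicate 2.

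The X chromosome carried fewer peaks per length than the autosomes in both females. X held 15.2 peaks per Mb in heart replicate 1 and 11.5 in heart replicate 2, against autosome means of 48.2 and 38.4, a ratio of 0.316 and 0.299. The lowest autosome was chromosome 3 with 35.7 and 27.7, and the highest chromosome 11 with 70.8 and 60.9. Promoter peaks marked 47.8% and 47.4% of the protein-coding genes of X, against 69.3% and 67.6% of autosomal ones. Kdm6a and Ddx3x, which are known to escape X inactivation, had peaks of 25.9 and 9.25 in heart replicate 1, against a median promoter height on X of 3.002. No test was made, since X is a single chromosome.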

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

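The tests on chromosome Y were set down before their results were seen; the comparison with random placements on Y was chosen only after. Both animals are labelled female, yet heart replicate 1 had 34 peaks on chromosome Y and heart replicate 2 had 48, a signal on a chromosome that females lack and that the report does not describe, although its overlap counts include these peaks. Of these 82 peaks, 21 and 22 lie in 1 block near the end of the chromosome (90717601 to 90744820), where the highest reached 3.70 and 11.02. DNA of a male animal is argued against by Ddx3y, Eif2s3y, Kdm5d and Uty, Y genes with widely used X partners, since 0 of 4 promoters listed an FDR under 0.05 in either library, and 0 of 183 protein-coding Y genes had a promoter peak. Reads from sequence that Y shares with X or the autosomes may be the source, since 85.4% of the peaks (70 of 82) hold a 32-base sequence found on another chromosome, against 54.9% of random placements on Y (45 of 82), a high level that limits the test. The 82 peaks are not independent, since some sites recur in both libraries, and the placements of both libraries share start positions. A peak also counted with 1 shared sequence, as did a block peak of heart replicate 1 with 0.769% of its sequences shared. The 12 peaks without any, all of which lie in the block that holds the highest signal, stay open, as do block peaks with few. All 39 peaks outside the block hold shared sequence, and the labels give 1 sex, so no biological explanation was tested.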

How the results depend on the processing

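Of 42 comparisons of a main value or count of calls with an alternative setting, 34 stayed within a set limit and 8 moved. For shares and ratios the limit was the SD between the values of the 2 libraries, and for counts of calls 1.5 times the count. For shared peaks, shared footprints and private peaks these values are 2 directions of 1 comparison. Their SDs of 9.96, 8.67 and 16.2 points are wide and are no spread between animals. Shared peaks at 56.3% against 63.2%, and private peaks at 27.5% against 41.6%, therefore counted as staying, which is little evidence of stability. For rho the limit was a confidence interval over the 62498 peak pairs, which treats peaks as independent and is no spread between animals. For the promoter share, leaving out either library could not exceed the SD, so those comparisons were no test. A kept count does not mean the same lists: 4 of the 6 promoter calls (fatty acid oxidation, endothelial, fibroblast, housekeeping), 4 of the 5 low promoter calls and 4 of the 9 locus calls (cardiac transcription factors, immediate early, endothelial, circadian clock) held in every setting run, and other lists gained or lost a call. With peaks above each list's median height, the mean share of shared peaks was 77.7%, rho was 0.788, the promoter share 43.0% and the X ratio 0.254; higher peaks are shared more often, as the report gives by height, and the cause of the other shifts was not tested. Promoter windows of 250 and 2500 bp gave promoter shares of 18.9% and 39.6%, as narrower and wider windows must, rho was 0.831 for peaks overlapping by 50% of both lengths, and 58.4% of footprints were shared in peaks of both animals; the cause was not tested. The longer lists gave 62.9% shared peaks, equal numbers 65.9%, an overlap of 50% 56.3%, and an FDR of 0.01 gave 27.5% of private peaks. The planned FDR of 0.1 was not run, because the track lists only values under 0.05. Without replicate 1 or 2, the promoter share ranged from 27.6% to 32.9%, called promoter lists from 8 to 9 (6 with both), called locus lists from 11 to 12 (9 with both), footprint motifs from 7 to 9 and distal motifs from 14 to 16. RUNX in distal peaks shared by both animals lay at -0.026; the cause was not tested. Alternatives chosen after seeing the data left out chromosome Y, peaks in runs (65.1% shared) and permutations with another CpG number. Of 117 named genes, the promoter call of 14 changed with the longer lists, 6 without runs, 5 within 250 bp and 3 above the median height. Depth is known only through the height step.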

Other observations

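All tests in this part except that of runs around sarcomere promoters were chosen only after the results were seen. Runs of close peaks lay over cardiac regulators in both animals. In heart replicate 2 they covered parts of Gata4, Mef2d, Hand2 and Prox1, 4 of the 20 cardiac transcription factors (percentile 99.9 among random lists), the calcium handling genes Ryr2, Atp2a2 and Kcnq1 (98.0), the endothelial genes Cdh5, Fli1 and Egfl7 (99.0) and the stimulus-induced Atf3 and Dusp1 (99.2). In heart replicate 1 they covered Gata6, Tbx5 and Mef2d (100) and, as the only immediate early gene, Junb (97.7). Of the cardiac transcription factors, only Mef2d held a run in both animals. Random lists were matched on gene length and not on numbers of peaks. Run peaks can also be distal peaks, so these calls are not independent of the distal counts. The runs with the most peaks in heart replicate 2 held 55 peaks in Sgms1, a sphingomyelin synthase gene (chromosome 19, 32325221 to 32358294), 44 at Lbh and 43 at Ackr2. Numbers of distal peaks within 10000 bp differed between animals in both directions, with 18 and 1 at Tnnt2, 7 and 40 at Ttn, which encodes titin, 4 and 21 at Mybpc3, a thick filament protein gene, and 0 and 17 at Myh6, in heart replicates 1 and 2. The 0 leaves out peaks of heart replicate 1 within 1000 bp of any annotated start. Among them is 1 of height 3.57 near Myh6 (chromosome 14, 54968401 to 54968720).

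Promoter peak heights also set some gene groups apart between the animals. Across 14241 promoters the log2 ratio of heart replicate 1 to heart replicate 2 had a median of 0.01 and an SD of 0.55. Of 22 lists with at least 5 such promoters, 4 lay within the highest 2.5% of lists matched on height and CpG: sarcomere (0.66), cardiac transcription factors (0.40, 14 of 19 higher), calcium handling (0.22) and, outside the heart lists, neuronal genes (0.33). Circadian clock genes lay just below that limit with a larger shift than calcium handling genes (0.33, 17 of 19 higher, percentile 97.45 against 97.53). Without members near runs the transcription factor median was 0.19 over 13 genes. The other heart lists did not stand out, with medians of 0.25 for stress and fetal (percentile 71.67), 0.21 for ventricular (77.66) and -0.11 for atrial genes (36.62). Endothelial (0.03), fibroblast (0.06) and smooth muscle (-0.09) genes lay near the median of all promoters, as did, against matched lists, fatty acid oxidation genes (0.20, percentile 76.2). Macrophage genes had a median of 0.53 (6 of 7 higher, percentile 93.97), lymphoid and adipocyte genes -0.48 each (6.43 and 9.95), and Schwann cell genes (-0.73 over 5) within the lowest 2.5%. The MEF2 motif in distal peaks differed by 1.38 on the log2 scale, rank 1 of 38 motifs, whose median difference was 0.28. The promoter peaks counted for some lists also lay in the window of another protein-coding gene, in 2 of 3 cases for germ cell genes, 3 of 8 for skeletal muscle, 2 of 17 for sarcomere and 0 of 22 for endothelial genes. Without runs, heart replicate 1 had 1.397 times as many peaks as heart replicate 2, while its height step is 1.10 times that of heart replicate 2, which would make heart replicate 2 the deeper library only if a step is 1 read.

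Sarcomere promoters were higher in heart replicate 1 in 15 of 17 genes, among them Csrp3 (2.29 against 0.902), Myl3 (2.62 against 1.02), Myh6 (2.49 against 1.09), Tnnt2 (2.04 against 1.03) and Mybpc3 (2.31 against 1.31), while Myl4 was lower (13.6 against 18.9). Lists matched on height and CpG had a mean median of 0.11, which argues against a library difference that depends on both as the whole source (percentile 99.95, in a list picked as the highest of 22). Runs of at least 10 peaks near these promoters are argued against as the whole source by a median of 0.66 over the 15 members without a run within 10000 bp. Shorter clusters of low peaks are not covered by that test, so splitting or lowering of promoter peaks of heart replicate 2 stays open. The region of Myh6 and Myh7, for example, held 33 peaks in heart replicate 2 and 8 in heart replicate 1. A larger share of cardiomyocyte nuclei in heart replicate 1 alone would move other cell types alike. The medians of 7 other lists spanned 1.25, at percentile 99.68 of 10000 reassignments of their members, which argues against that share as the only difference between the libraries. The ends of the span were lists of 5 Schwann cell and 7 macrophage genes, while endothelial (0.03), fibroblast (0.06) and smooth muscle (-0.09) genes moved alike. The test therefore cannot decide whether that share raised the sarcomere promoters. That share and a difference of another kind between the animals may remain as hypotheses found on the same data. The design has 1 group and n = 2, so beyond the share of cardiomyocyte nuclei no biological explanation was tested.

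Runs of at least 10 close peaks held 10.2% of the peaks of heart replicate 2 and 0.942% of those of heart replicate 1. In heart replicate 2, where 33 of 593 runs overlapped a run of the other animal, their peaks were low (median 0.216 against 0.958). They were shared in 20.2% of cases, against 29.0% of peaks outside runs of the same height. Footprints covered 7.07% of their bases, against 17.5% in all peaks outside runs. This footprint comparison was not matched on height, so the low height of run peaks may account for it. Repeats as the main content of the runs are argued against by a soft-masked share of 18.5% against 36.4% of the genome. The runs of heart replicate 1 held less (14.8%), and the share in peaks outside runs was not measured, so a smaller part of repeats stays open. A difference in depth, and a copy gained in the strain, which both animals would carry, are argued against as the whole source of the runs of heart replicate 2, since 28.4% of run peaks held an FDR under 0.05 in heart replicate 1, against 36.6% of peaks outside runs of the same height (a gap of -8.28 percentage points, from -9.66 to -6.98 in 95% of resamples of the genome). For the runs of heart replicate 1 the gap went the other way. Of their 1095 peaks, 81.8% held an FDR under 0.05 in heart replicate 2, against 75.2% of peaks outside runs of the same height. A lower local threshold of peak calling may contribute and stays open, since 28.8% of run peaks lie under the height that 95% of other peaks exceed, a share between those set for and against it, as does broad accessibility in 1 animal, and no biological explanation was tested.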
